A study of Mus musculus with 3 samples.

How the data were processed

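RNA-seq libraries from 3 sorted populations of mouse intestinal epithelium (iCD8a, ILC1 and CD11b+, all from RAG-2-deficient mice) were analysed, with 1 library per population. Samples were grouped by the cell type label. The 3 sample titles carry 1 shared date, so no batch could be set apart. Per the series' design text, the authors sequenced on an Illumina HiSeq instrument, aligned reads with TopHat and counted them per gene with HTSeq. The submitters' processing notes list CASAVA 1.9 and TopHat2. The genome build, the annotation, the strand setting and the counter's version are not given in the sources used here, so no coordinates are printed. The deposited files hold raw read counts per Ensembl gene, with no normalization by the authors. The FPKM values that the design text mentions were not used here.

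Each file ends with 5 rows that name no gene, which stayed out of library sizes and comparisons. As shares of all rows, alignments that were not unique came to 26.9% in iCD8a, 34.5% in ILC1 and 30.5% in CD11b+. Reads in no gene came to 9.31%, 11% and 8.56%, and ambiguous reads to 1.08%, 0.889% and 0.922%. Because reads that align to several places were not counted, genes with near-identical copies (Klra, H2-Q, Defa and granzyme genes) have uncertain levels. Without a stated strand setting, a gene and an overlapping or antisense partner cannot be told apart. Mitochondrially encoded genes took 1.60%, 2.09% and 9.53% of gene counts.

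Gene symbols, biotypes and the mitochondrial chromosome were taken from the GENCODE mouse annotation by Ensembl ID. Of 37224 IDs, 35449 matched, and the 1775 others held 0.338%, 0.484% and 0.430% of gene counts. TMM factors (edgeR 4.0.16 in R 4.3.3) were 1.09 for iCD8a, 0.992 for ILC1 and 0.925 for CD11b+. Folds are ratios of TMM-normalized counts with 95% exact conditional binomial (Clopper-Pearson) intervals, computed with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Figures were drawn with matplotlib 3.10.9. Reads without molecular identifiers are not independent molecules, so these intervals and the floor of 3 counts cover counting error only. For a gene at 0 counts in a library, the near bound of the interval is given in place of a fold. With 1 library per group no quasi-likelihood test has residual degrees of freedom, so edgeR and DESeq2 1.42.0 were used for normalization factors alone and no p-value was computed.

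The design was fixed before the data were examined. A gene was counted between 2 libraries when its fold was at least 4, the near bound of the interval at least 2, and the CPM at least 5 in the higher library, and as enriched in a population when it passed against both others. Similarity was taken over genes with at least 5 CPM in any library. For 31 gene lists (643 symbols, 11 of them unmatched), the median log2 ratio with a prior count of 0.5 was taken over members with at least 1 CPM in any library. Its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression, describes these libraries and is not a test. Lists share members: 11 of the 32 genes in the natural killer cell and ILC1 list and 11 of 32 in the macrophage list stand in another list. Named were Rag1, Rag2 and the sort markers, the 12 protein-coding genes per pair and direction with the largest near bound at 20 CPM or more, the 10 such enriched genes per population, and members of the lists as examples. Clone-style symbols were left out of the ranked names, and some genes that the rule names are not reported here.

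The steps were tested on simulated Poisson counts with 200 changed genes in the iCD8a and ILC1 comparison, run on 10287 genes. The rule recovered 0% of genes simulated at 2-fold, 40.0% at 4-fold and 100% at 8-fold and at 16-fold, and called 0 unchanged genes. Between ILC1 and CD11b+, intervals covered the true ratio for 95.6% of unchanged genes above a count minimum. Exact intervals on Poisson counts reach about 95% by construction, and coverage for changed genes was not checked. Of 200 random lists, 10 lay outside the central 95%, and a list planted at 4-fold reached percentile 100. The simulation holds counting error and no spread between animals. All libraries were drawn from a common profile apart from the 200 changed genes. A planted list stands out there by construction, and the many genes apart between the real libraries were not imitated.

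Alternatives fixed beforehand were unscaled CPM by total count, DESeq2 median-of-ratios and upper-quartile factors in place of TMM, other CPM minimums, a fold of 8, libraries thinned to 21678113 counts each, protein-coding genes only, and removal of the 50 most abundant genes of each library. For similarity they were Pearson's r, thinning and removal of the epithelial lists, and for list medians a prior count of 2, other minimums and members of 1 list only. Removal of the 37 mitochondrially encoded genes was added after seeing the data.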

Results

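RNA was sequenced from 3 immune cell populations sorted from the gut epithelium of mice that lack RAG-2, a recombinase subunit needed to assemble the antigen receptors of T and B cells. The iCD8a library came from cells that carried CD45, a surface marker of leukocytes, and CD8α. Group 1 innate lymphoid cells, sorted as NKp46-positive and NK1.1-positive, gave the ILC1 library. Myeloid cells, sorted as CD45-positive, CD8α-negative and CD11b-positive, gave the CD11b+ library. Each population had 1 library, so no difference given here has a replicate check, and none could be tested between populations. Whether a library came from 1 mouse or a pool of several is not given in the sources used here. Reads counted on genes totalled 21678113 for iCD8a, 22181660 for ILC1 and 30511296 for CD11b+. Levels are CPM, a gene's count relative to its library's total, scaled by TMM factors, and the range after each fold is its 95% exact counting interval, which covers counting error between 2 libraries and not the spread between animals.

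Rag2 (ENSMUSG00000032864), the gene named by the genotype, had 0 counts in each library, which allows at most 0.127 CPM in iCD8a, 0.136 CPM in ILC1 and 0.106 CPM in CD11b+. Rag1, its partner, had 0, 0 and 1 counts. Mature lymphocytes and myeloid cells carry little transcript of either gene in any genotype, so this is a weak check of the label. The sort markers followed the gates. Cd8a (ENSMUSG00000053977) stood at 2636 CPM in iCD8a, 4.41 in ILC1 and 28.3 in CD11b+, and Ncr1 (ENSMUSG00000062524), which encodes NKp46, at 1.44, 396 and 2.23. Klrb1c, which encodes NK1.1, was found outside the ILC1 gate as well, at 207 CPM in iCD8a against 546 in ILC1 and 14.7 in CD11b+. Itgam (ENSMUSG00000030786), which encodes CD11b, stood at 845 CPM in CD11b+ and was also counted in iCD8a, at 362, and in ILC1, at 187. Ptprc, which encodes CD45, was at 2136, 2695 and 1795 CPM.

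**Figure D1:**
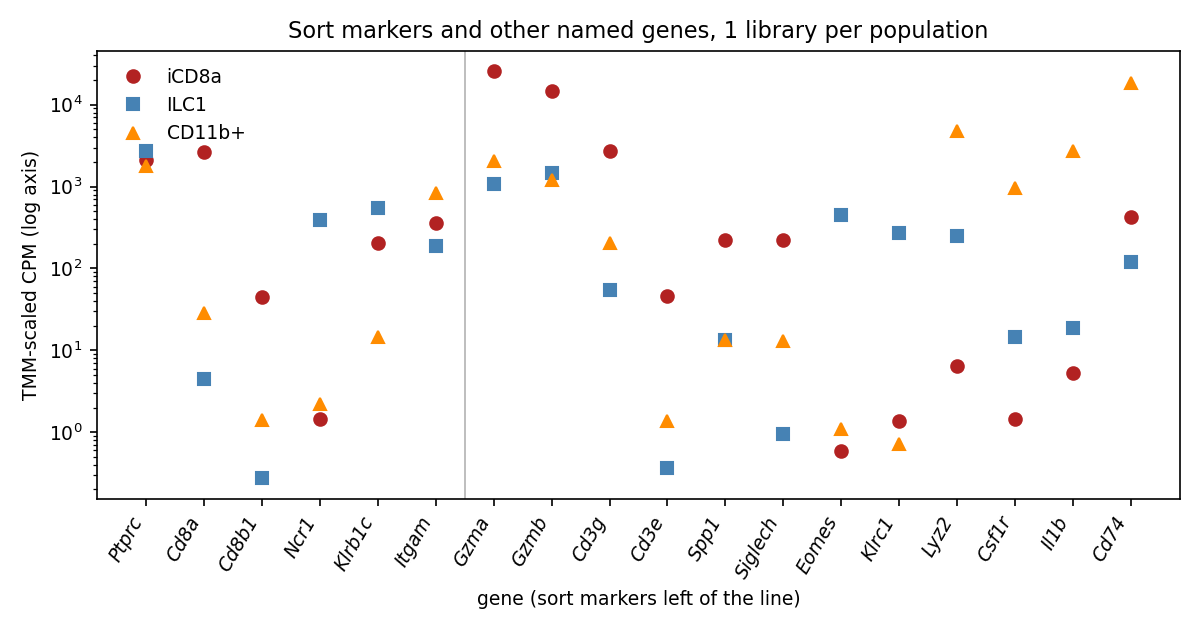
TMM-scaled CPM on a log axis for the 6 sort markers, left of the line, and 12 other named genes, with 1 point per library and no error bar because each population had 1 library. Cd8a stands highest in iCD8a at 2636 CPM, Ncr1 in ILC1 at 396 CPM and Itgam in CD11b+ at 845 CPM.

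The series' design text sets the 3 transcriptomes side by side, which asks how the iCD8a cells relate to group 1 innate lymphoid cells and to myeloid cells of the same tissue. Across 11063 genes with at least 5 CPM in any library, Spearman's rho was 0.891 between iCD8a and ILC1, 0.719 between iCD8a and CD11b+, and 0.725 between ILC1 and CD11b+. These correlations run across genes, which are not independent replicates. The SD of the log2 ratios was 1.39 for iCD8a and ILC1, 2.07 for iCD8a and CD11b+ and 2.0 for ILC1 and CD11b+. A gene was counted as apart when its fold was at least 4, the near bound of its interval at least 2 and its level at least 5 CPM in the higher library. By that rule 356 genes were higher in iCD8a than in ILC1 and 494 were lower, 663 were higher in iCD8a than in CD11b+ and 1447 lower, and 645 were higher in ILC1 than in CD11b+ and 1391 lower. The numbers higher in CD11b+ include intestinal epithelial genes, 30 of 34 listed against iCD8a and 32 of 34 against ILC1.

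**Figure D2:**
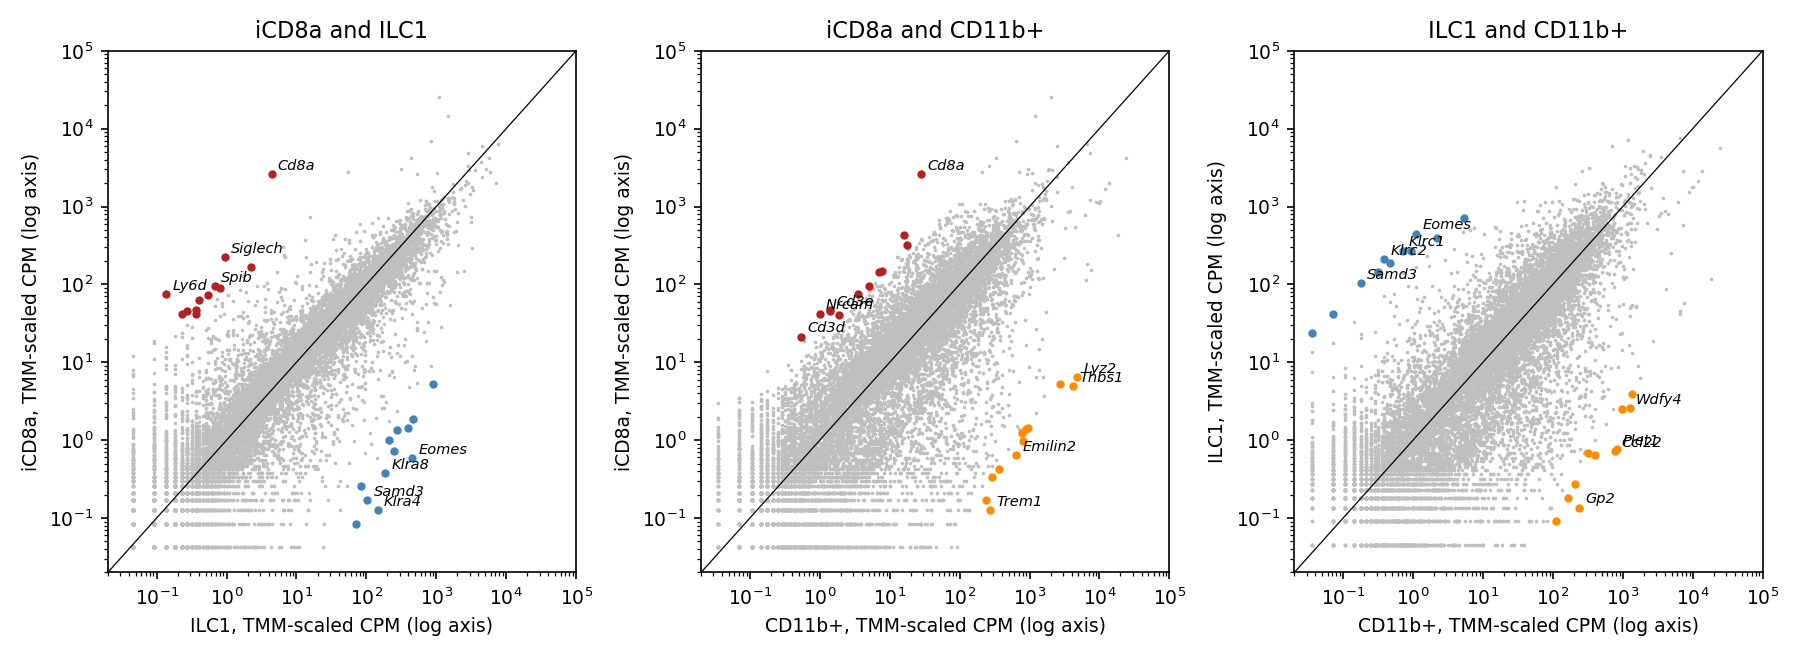
Each point is a gene with counts in both libraries, placed by its TMM-scaled CPM on log axes, and the line marks equal levels. Coloured points are the genes named by the rule for each direction (red higher in iCD8a, blue in ILC1, orange in CD11b+), with up to 4 per direction written out. Cd8a lies far above the line against both other libraries, and the iCD8a and ILC1 panel is the narrowest, with an SD of log2 ratios of 1.39.

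Set against group 1 innate lymphoid cells, the iCD8a library held few transcripts of many natural killer receptors and carried more of 2 granzymes. Eomes (ENSMUSG00000032446), a T-box transcription factor of natural killer cells, was 757-fold higher in ILC1 (451 to 1385). Klrc1, which encodes the inhibitory receptor NKG2A, was 201-fold higher (142 to 294), and Il18r1, a receptor chain for interleukin 18, was 249.6-fold higher (186 to 344). Gzma and Gzmb, serine proteases of cytotoxic granules, reached 25743 and 14623 CPM in iCD8a, 23.9-fold (23.6 to 24.2) and 10.1-fold (9.98 to 10.2) above ILC1. Spp1, which encodes the secreted phosphoprotein osteopontin, was 16.7-fold higher in iCD8a (14.8 to 18.8).

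Of the 32 measured members of the natural killer cell and ILC1 list, 18 were higher in ILC1 and 2 in iCD8a, Gzma and Ccl5, with a median log2 ratio of iCD8a over ILC1 of −4.98. The Klra4 and Klra8 receptors of the Ly49 family were 1146-fold (392 to 5559) and 490.1-fold (258 to 1073) higher in ILC1. Ly49 genes are near-identical copies whose reads can be split between them or dropped, so their single values are uncertain. Tbx21, which encodes T-bet, and Il2rb, the shared receptor chain for interleukins 2 and 15, did not pass the rule, at 108 against 330.4 CPM and 3288 against 2825 CPM. Samd3, Zfp683, Atp8b4, Ms4a4b and Xcl1 were higher in ILC1 by 611, 330.4, 331, 341 and 37.8-fold, of which Zfp683 rests on 3 counts in iCD8a (interval 113 to 1605). Among innate lymphoid transcription factors, 4 of 19 were higher in ILC1 and 0 in iCD8a. They included Eomes, Tcf7 (502 against 8.89 CPM) and Bach2.

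The T cell receptor and CD3 list was divided, with 6 of 17 measured members higher in iCD8a and 4 in ILC1. Cd3g, a chain of the CD3 signalling complex, was at 2749 CPM in iCD8a and 54.1 in ILC1, a 50.8-fold difference (48 to 53.9), and Cd3e was 129-fold higher in iCD8a (65 to 298). Cd247, the zeta chain of the same complex, and the costimulatory receptor Cd28 were higher in ILC1, at 64.8 against 14.2 CPM and 75.9 against 3.64 CPM. Of 16 proximal signalling genes, the surface receptor Cd7 was higher in iCD8a (4223 against 435 CPM), and Cd2, Sh2d1a and Thy1 were higher in ILC1. Lck and Zap70, kinases that act below antigen receptors, stood close, at 709.8 against 573 CPM and 370.4 against 381 CPM. Of 15 cytotoxic effectors, Gzma and Gzmb passed the rule and 0 were higher in ILC1, while the pore-forming protein Prf1 was at 284 against 325 CPM. Of 21 tissue residency genes, Itgae, the integrin chain CD103 that binds E-cadherin on epithelium, was higher in iCD8a (9.5-fold, 9.27 to 9.74) and Zfp683 in ILC1.

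Cytokine transcripts were more abundant in ILC1 for 12 of 24 measured members and in iCD8a for 2, Spp1 and Tnfsf13b. Ifng, the type 1 cytokine interferon gamma, was at 208 CPM in ILC1 and 6.94 in iCD8a, and Tnfsf14 was at 114 against 1.23. Among ILC3 genes 9 of 16 were higher in ILC1 and 0 in iCD8a, among them Il22 (83.1 against 4.82 CPM), Kit (934 against 150.1) and the interleukin 7 receptor chain Il7r (259 against 22.9). Of 11 measured ILC2 genes, Areg, Calca and Rora were higher in ILC1. Immediate early and dissociation response genes were higher in ILC1 for 8 of 23 members, with a median log2 ratio of iCD8a over ILC1 of −1.63. Nr4a1, induced within minutes of stimulation, was at 2455 against 150.3 CPM and Dusp2 at 854 against 8.84.

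Markers of other cell types also differed between these libraries. Plasmacytoid dendritic cell genes were higher in iCD8a for 4 of 10 members and lower for 0, with a median at percentile 100 among 10000 random lists of matched expression. Siglech, a surface lectin of plasmacytoid dendritic cells, was 235-fold higher (153 to 379.5) and Spib, a transcription factor of the same cells, 139-fold higher (84 to 249). Ly6d was 555-fold higher (189.7 to 2696), with 3 counts in ILC1. Of 19 dendritic cell genes, 8 were higher in iCD8a and 2, Ly75 and Zbtb46, in ILC1. Of 31 macrophage and monocyte genes, 12 were higher in ILC1 and 3 in iCD8a. Lyz2, a lysozyme of myeloid cells, stood at 252 CPM in ILC1 and 6.52 in iCD8a, and Fn1, which encodes fibronectin, at 271 and 1.4. Intestinal epithelial genes were near level, with a median log2 ratio of 0.06 over 34 genes, of which Epcam and Cdh17 were higher in iCD8a.

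Set against the CD11b+ library, the iCD8a library carried more lymphocyte signalling and cytotoxic transcripts and less of many typical of phagocytes. Some phagocyte genes were near level, such as Fcgr3 (182 CPM in iCD8a, 208 in CD11b+) and Ctsl (99.3 and 104). Cd8a was 93.3-fold higher in iCD8a (87 to 100.2), Cd3e 33.8-fold (24.6 to 47.8) and Cd200r2 26.5-fold (24.2 to 29.2). Tigit, an inhibitory lymphocyte receptor, was 18.9-fold higher (16.5 to 21.7), and Tnfrsf9, the costimulatory receptor 4-1BB, 18.3-fold (16.7 to 20.1). Lyz2 was 743-fold higher in CD11b+ (635 to 876), Csf1r, the receptor for macrophage growth factor, 667-fold (477 to 963), and the inflammatory cytokine Il1b 513-fold (431 to 617).

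Of 16 proximal signalling genes, 13 were higher in iCD8a and Thy1 was higher in CD11b+, with a median log2 ratio of 3.18. Of 17 T cell receptor and CD3 genes, 12 were higher in iCD8a and 0 in CD11b+, and of 15 cytotoxic effectors 9 and 0. Gzma was 12.6-fold (12.5 to 12.7) and Gzmb 12.2-fold (12.1 to 12.3) higher in iCD8a, yet both stayed abundant in CD11b+, at 2043 and 1198 CPM. The 11 signalling genes with at least 100 CPM in iCD8a stood in CD11b+ at a median of 10.2% of their iCD8a level. In the opposite direction, 25 of 31 macrophage and monocyte genes, 16 of 17 genes of MHC class II antigen presentation and 13 of 19 dendritic cell genes were higher in CD11b+. Trem1, a receptor that amplifies myeloid inflammation, was 2130.4-fold higher (729 to 10333) with 3 counts in iCD8a, and Thbs1, which encodes thrombospondin 1, 844-fold (704 to 1022). Cd74, the chaperone of MHC class II, was at 18551 CPM in CD11b+ and 430.3 in iCD8a. Of 28 genes of phagocytosis and bacterial killing, 17 were higher in CD11b+, including the oxidase subunits Cybb and Ncf4, and Nox1 was higher in iCD8a (13.5 against 1.06 CPM). Of 30 pattern recognition and inflammasome genes, 18 were higher in CD11b+ and 0 in iCD8a, with the fungal sensor Clec7a at 1629 against 3.64 CPM.

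Of 24 cytokine genes, 15 were higher in CD11b+ and Spp1 was higher in iCD8a (16.9-fold, 15.3 to 18.9). Of 30 chemokine genes, 17 were higher in CD11b+, such as Ccl22, a chemokine that attracts regulatory T cells (629-fold, 438 to 939), and 4 in iCD8a, Ccl5, Ccr9, Cxcr3 and Cxcr6. Immediate early and dissociation response genes were also higher in CD11b+, for 10 of 23 members against 0 in iCD8a, with a median log2 ratio of −1.53, and their median for ILC1 over CD11b+ was 0.63, inside the central 95% of random lists. The CD11b+ library also held more transcripts of epithelial cells. Intestinal epithelial genes were higher there for 30 of 34 members, with a median log2 ratio of iCD8a over CD11b+ of −3.08 and quartiles of −3.29 and −2.86. Reg3b, an antimicrobial lectin of enterocytes, was at 442 CPM against 55.1. Goblet, Paneth, tuft and enteroendocrine cell genes were higher there for 15 of 21. Among other myeloid lists, eosinophil genes were higher in CD11b+ for 5 of 6 measured from a list of 12. Members below 1 CPM in every library were left out, among them Epx, with 5 counts in CD11b+. Neutrophil genes were higher there for 6 of 11 measured from a list of 18. Mitochondrially encoded genes took 9.53% of gene counts in CD11b+ and 1.60% in iCD8a.

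The ILC1 library carried natural killer transcripts at levels far above CD11b+. Klrc2, an activating receptor chain, was 535-fold higher in ILC1 (299 to 1073) and Eomes 408-fold (287 to 601). Ncr1 was 178-fold higher (139 to 231), and Xcl1, a chemokine that attracts dendritic cells, 133-fold (113 to 157). Sh2d1a, an adaptor of lymphocyte receptors, had 0 counts in CD11b+ and 26.4 CPM in ILC1, and the near bound of its interval was 202-fold. Plet1 (ENSMUSG00000032068), a surface protein of some dendritic cells, was 1053-fold higher in CD11b+ (658 to 1808), Ccl22 1061-fold (653 to 1857) and Gp2 1741-fold (596 to 8446).

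Of 32 natural killer and ILC1 genes, 28 were higher in ILC1 and 0 in CD11b+, with a median log2 ratio of 4.64. Of 16 proximal signalling genes 14 were higher in ILC1, and of 17 receptor and signalling genes of the common gamma chain family 8 were, among them Il2ra (139.5 against 3.47 CPM). Innate lymphoid transcription factors were higher in ILC1 for 10 of 19, and Prdm1 and Id3 were higher in CD11b+. Macrophage and monocyte genes were higher in CD11b+ for 25 of 31 and MHC class II genes for 16 of 17, with H2-Ab1 at 7529 CPM against 57.7, while Lyz2 in ILC1 stood at 5.20% of its CD11b+ level. Ccr2, a chemokine receptor of monocytes, was level, at 355 CPM in ILC1 and 331 in CD11b+. Wdfy4 and Cd209a, genes of dendritic cells, were 483-fold (372 to 637) and 461-fold (279 to 824) higher in CD11b+, and Il1r2, a decoy receptor for interleukin 1, 351-fold (284 to 439). Procr, the protein C receptor, had 0 counts in ILC1 and 64.1 CPM in CD11b+, with a near bound of 382-fold. Epithelial genes were again higher in CD11b+, for 32 of 34 members, with a median log2 ratio of ILC1 over CD11b+ of −3.15.

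**Figure D3:**
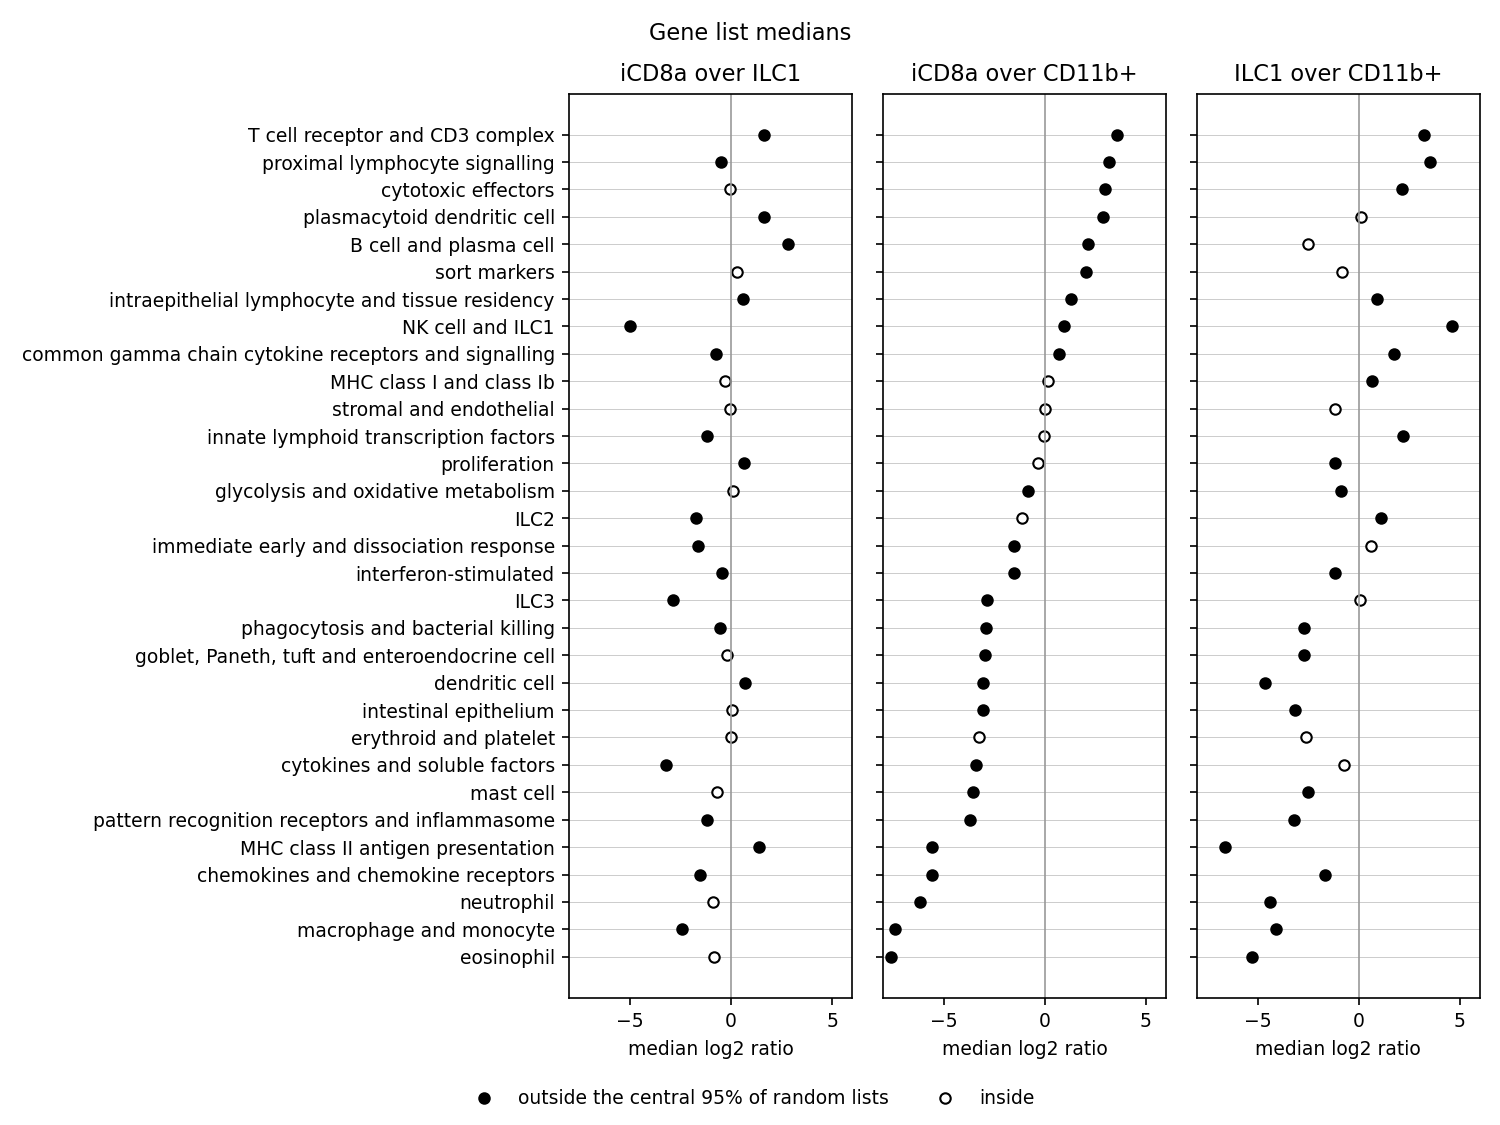
Median log2 ratio of the measured members of each of 31 gene lists, for the 3 pairs of libraries, where a value above 0 means higher in the library named first. Filled points lie outside the central 95% of 10000 random lists of matched expression and open points inside it. The natural killer cell and ILC1 list stands at −4.98 for iCD8a over ILC1 and 4.64 for ILC1 over CD11b+.

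Genes that passed the rule against both other libraries numbered 168 for iCD8a, 186 for ILC1 and 1126 for CD11b+. The number for CD11b+ includes intestinal epithelial genes, whose median log2 ratio was −3.08 for iCD8a over CD11b+ and −3.15 for ILC1 over CD11b+. The source of these epithelial transcripts was not tested, so the number does not describe CD11b+ cells alone. Enriched genes with the largest near bound in iCD8a included Cd8a, Nrcam, Cd3e, Cd8b1, Ly6d, Glp1r, Siglech, Spp1 and Arfgef3. Glp1r, the receptor for the gut hormone GLP-1, was at 94.4 CPM in iCD8a, 2.73 in ILC1 and 5.07 in CD11b+, and the cell adhesion gene Nrcam at 42.2, 0.227 and 0.993. For ILC1 they were Eomes, Klra4, Samd3, Klra8, Klrc1, Ncr1, Klrc2, Zfp683, Klra9 and Klra1, of which 4 are Ly49 genes. For CD11b+ they were Plet1, Gp2, Ccl22, Chil3, Stra6l, Mefv, Retnlg, Rtn1, Ccl17 and Gpr141. Mefv, which encodes the inflammasome sensor pyrin, was at 286 CPM in CD11b+, and Chil3, a chitinase-like protein of myeloid cells, at 207. In reverse, 244 genes were lower in iCD8a than in both others, 155 in ILC1 and 293 in CD11b+.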

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

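The tests of explanations in the 3 patterns below were all chosen after the values had been seen, whereas the signalling, plasmacytoid dendritic cell and dendritic cell lists were fixed before. Some of each library lay outside the comparisons, in the rows that name no gene. Alignments that were not unique made up 26.9% of all rows in iCD8a, 34.5% in ILC1 and 30.5% in CD11b+. Reads in no gene made up 9.31%, 11% and 8.56%. IDs outside the annotation stayed in the library sizes and in the numbers of genes apart, but had no symbol and could not be named. They took 0.338%, 0.484% and 0.430% of gene counts. The most abundant of them in ILC1, ENSMUSG00000089672, was at 98.6, 1213 and 469 CPM in the same order.

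Transcripts abundant in iCD8a were present in the CD11b+ library: 11 members of the signalling list with at least 100 CPM in iCD8a stood in CD11b+ at a median of 10.2% of their iCD8a level (quartiles 9.67% and 13.2%). Carry-over of RNA, reads or cells from the CD8α-positive sort would bring Cd8a at a like share. Cd8a stood at 1.07% (counting interval 0.998% to 1.15%), which argues against carry-over as the source of the 10.2% share but not against a smaller carry-over. It stood below all 93 other genes that were higher in iCD8a than in ILC1 with at least 50 CPM (quartiles 8.19% and 37.5%). That rank adds little, because the 93 were chosen against ILC1 alone and include genes higher in CD11b+, such as Cybb (129 against 988 CPM). The minimum of 50 CPM also left out Cd3e, at 2.96%, and Cd8b1, at 3.14%. ILC1 cells in the CD11b+ library are also argued against, since the highest of Ncr1, Eomes, Klrc1 and Klre1 stood at 0.563% of its ILC1 level. CD8α-negative lymphocytes in the CD11b+ gate may be a source for the 11 genes. The upper quartile of their shares was 1.36 times the lower, as a common source at a common share would give. Other genes stood lower, with Cd3e at 2.96%, Siglech at 5.76% and Spp1 at 5.90%. The minimum of 100 CPM, chosen after the values were seen, left out list members that break the common share. Cd2 was at 0.677 CPM in iCD8a and 1.88 in CD11b+, Thy1 was higher in CD11b+, and Sh2d1a had no counts there. The gate for CD11b was also meant to remove lymphocytes that lack it. Itgam, which encodes CD11b, was counted in iCD8a and ILC1 as well, so the gate need not remove all lymphocytes. Expression by the CD11b+ cells themselves of the genes abundant in iCD8a was not tested and stays open.

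Plasmacytoid dendritic cell transcripts, from a list of 10 genes of which 2 stand in another list, were higher in iCD8a for 4 against ILC1 and 6 against CD11b+, with Siglech at 224 CPM, and MHC class II genes had a median log2 ratio over ILC1 of 1.38 (percentile 100 of random lists), with 1 of 17, H2-Oa, past the rule. Cells of the sorted CD11b+ population as a whole are argued against. Cd74 stood in iCD8a at 2.32% of its CD11b+ level while the highest of Lyz2, Csf1r, Il1b and Spi1 stood at 0.775% (0.648% to 0.920%). No dendritic cell gene was in that test, so dendritic cells of the CD11b+ sort stay open as a source. Levels of such genes varied, with Flt3 at 35.1 CPM in iCD8a and 280 in CD11b+, and Cd24a at 5.71 and 298. Of 10 further plasmacytoid genes, written after the enriched genes had been seen and leaving those out, 9 were detected and 3, Bcl11a, Grm8 and Ptprf, exceeded both other libraries in iCD8a by more than counting error, a looser limit than the size rule, which 0 of them passed against both; of 7 further genes of CD8α-positive classical dendritic cells, 0 met either limit, although by the size rule 8 of 19 genes of the dendritic cell list fixed before were higher in iCD8a than in ILC1 and 2 were lower, and Clec9a, a lectin of such cells, was 121-fold above ILC1 (46.8 to 444) and 5.52-fold above CD11b+ (4.49 to 6.83). Counts this low met the bounds first set against both cell types, but those bounds were wrong and exclude neither, because the lists left out genes already seen to be enriched and because a few such cells need not exceed a CD11b+ library with dendritic cell transcripts of its own, such as Wdfy4 at 1249.8 CPM. Against ILC1 alone, the further plasmacytoid genes Bcl11a (20.3 against 0.318 CPM), Lifr (13.6 against 0.545) and Ptprf (26.3 against 1.64) were higher in iCD8a. Upb1, Grm8 and Dirc2 were higher too, and Mctp2, Tex2 and Atp1b1 were not. Of the further classical genes, Rab7b (3.64 against 0.454 CPM) and Cadm1 were higher, Snx22 and Ifi205 were not, and the rest had few counts. These tests do not tell plasmacytoid from classical dendritic cells. Nor does the dendritic cell list fixed before, which was not limited to the CD8α-positive classical type. Among dendritic cell genes, Flt3 (35.1 against 0.682 CPM) and Cd209a (9.39 against 0.682) were higher in iCD8a than in ILC1. Batf3 (1.735 against 1.545 CPM) and Cd24a (5.71 against 5.77) were near level. Expression by the iCD8a cells themselves was not tested and stays open.

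Macrophage and monocyte genes were higher in ILC1 than in iCD8a for 12 of 31 and lower for 3, with Lyz2 in ILC1 at 5.20% of its CD11b+ level, C1qb at 10.9% and Fn1 at 30.2%, but Csf1r at 1.501% and Il1b at 0.698%. Cells or RNA of the sorted CD11b+ population as a whole are argued against, since the highest of the MHC class II genes Cd74, H2-Aa and H2-Ab1 stood at 0.766% of its CD11b+ level (0.724% to 0.809%). A list of 10 genes of macrophages of a peritoneal type was written after the enriched genes had been seen, leaving those out. Of these, 4, Vsig4, Selp, Cxcl13 and Tgfb2, exceeded both other libraries in ILC1 by more than counting error and 0 by the size rule. That decides nothing for the same reasons. Against iCD8a alone, Serpinb2 (27.9 against 0.169 CPM), F5 (11.6 against 0.212) and F10 (6.50 against 0.0846) were also higher in ILC1. These genes stood higher still in CD11b+, at 40.1, 90.4 and 65.0 CPM. Macrophages unlike the CD11b+ sort as a whole, among them a part of that sort, were not tested further and stay open. Expression by the ILC1 cells themselves was not tested further either and stays open. The gate for NKp46 and NK1.1 was meant to remove macrophages.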

How the results depend on the processing

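With 1 library per population, no replicate or doubted library could be left out, and depth limits the precision of genes with few counts. No paired analysis was possible because each group has 1 library. The added removal of mitochondrially encoded genes was chosen after seeing the data. Counts of genes apart or enriched stayed within 1.5 times under other normalization factors, thinning, protein-coding genes only, and removal of the 50 most abundant or the mitochondrially encoded genes. CPM by total count, without TMM factors, moved the median of all genes by 0.14 (iCD8a over ILC1), 0.24 (iCD8a over CD11b+) and 0.10 (ILC1 over CD11b+) on the log2 scale. Looser and stricter limits changed the counts by construction. In the order iCD8a over ILC1, ILC1 over iCD8a, iCD8a over CD11b+, CD11b+ over iCD8a, ILC1 over CD11b+ and CD11b+ over ILC1, no CPM minimum gave 642, 868, 1036, 2454, 976 and 2286 genes, with 286, 298 and 1796 enriched in iCD8a, ILC1 and CD11b+. At least 20 CPM gave 186, 299, 438, 936 and 881 genes (all but ILC1 over CD11b+, which stayed within 1.5 times) and 95, 117 and 712 enriched. A fold of 8 gave 202, 305, 273 and 297 genes (iCD8a over ILC1, ILC1 over iCD8a, iCD8a over CD11b+, ILC1 over CD11b+) and 81, 113 and 720 enriched. Similarity moved beyond counting error with the genes used, but iCD8a and ILC1 remained the closest pair under every alternative run. In the order iCD8a and ILC1, iCD8a and CD11b+, ILC1 and CD11b+, rho was 0.918, 0.797 and 0.803 at 1 CPM and 0.847, 0.60 and 0.606 at 20 CPM, and Pearson's r was 0.875, 0.675 and 0.694. The SD of log2 ratios was 1.49, 2.16 and 2.07 at 1 CPM and 1.33, 2.02 and 1.95 at 20 CPM, and 2.06 for iCD8a and CD11b+ after thinning. Without the epithelial lists rho with CD11b+ was 0.722 for iCD8a and 0.728 for ILC1. The list of ILC2 genes, ILC1 over CD11b+, reversed from a median log2 ratio of 1.10 to −0.28 with no expression minimum, which took in 13 members in place of 11, the others below 1 CPM. With members of 1 list only, 3 list medians came to lie inside the central 95% of random lists, phagocytosis and bacterial killing in iCD8a over ILC1 (−0.56 to −0.24) and, in ILC1 over CD11b+, ILC2 (1.10 to 0.60) and eosinophil (−5.30 to −3.35), and 6 others moved. At 5 CPM or more the mast cell median in ILC1 over CD11b+ also did (−2.51 to −3.61), and 8 moved, of which ILC2 in iCD8a over CD11b+ turned from −1.10 inside that range to 1.25 above it. No minimum put 4 medians outside the range, with direction kept, and moved 1. Total counts moved 9 and upper-quartile factors 5, and a prior count of 2, genes at 0 set to their bound and removal of mitochondrially encoded genes moved 1 each.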

Other observations

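The chains of the CD3 complex were far from level within the iCD8a library, where Cd3g was at 2749 CPM, Cd3e at 46.7, Cd3d at 21.4 and Cd247 at 14.2. In ILC1 Cd3g was at 54.1 CPM and Cd247 at 64.8. CPM is not corrected for transcript length, so small gaps between genes of 1 library rank nothing. Constant segments of T cell receptor genes were transcribed as well, with Trbc1 at 214 CPM in iCD8a and 222 in ILC1, and Tcrg-C4 at 251 and 81.9. Immunoglobulin heavy chain transcripts stood highest in iCD8a, with Ighm at 469 CPM against 285 in ILC1 and 152 in CD11b+, and Igha at 212, 30.4 and 17.9. Of the 9 measured B cell and plasma cell genes, Cd79b, Igha, Mzb1 and Blnk were higher in iCD8a than in ILC1.

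Of 23 MHC class I and class Ib genes, H2-Q7 and H2-Q10 were higher in ILC1 than in iCD8a and 0 were lower. H2-Q7 was at 3094 CPM in ILC1, 636 in iCD8a and 334 in CD11b+, values that paralogous reads make uncertain, and H2-T23 at 375, 441 and 418. B2m, the shared light chain, was at 2912, 2909.6 and 1828 CPM in iCD8a, ILC1 and CD11b+. Interferon-stimulated genes were higher in CD11b+ than in iCD8a for 8 of 25 members, among them the antiviral gene Oas2 (67.8 against 0.592 CPM). Of 22 proliferation genes, 0 passed the rule between iCD8a and either library, while their median log2 ratio was 0.65 over ILC1, at percentile 99.92 of random lists, and −0.34 over CD11b+, at percentile 3.29. Car2, a carbonic anhydrase, was at 504 CPM in iCD8a and 1127 in ILC1, against 76.5 in CD11b+. The 12 mitochondrially encoded protein genes measured were all lower in iCD8a than in CD11b+, with a median log2 ratio of −2.88, and all lower in ILC1, with a median of −2.45.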
